A study of Zea mays with 50 samples.

How the data were processed

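Isolated maize leaf protoplasts (plant cells with the wall digested away) from inbred B73 were made to express 1 of 23 putative regulators of reproductive phasiRNAs (phased small RNAs made from long precursor transcripts in anthers), and their polyadenylated RNA was sequenced. Per the labels, the cells came from leaves of more than 10 etiolated seedlings aged 10 to 12 days grown at 25 °C, and control cells expressed GFP alone from a 35S promoter. ZFL2 carried GFP at its C-terminus and the other regulators at their N-terminus. Each of the 50 libraries belongs to 1 of 4 protoplast preparations (preps). OCL4, ZHD5, TCP23, ZFL2, NAC29, CSD4, ZIM13, NAC119, HSF2, DOF25 and bHLH103 were expressed in preps 1 and 3. The other 12 regulators, bHLH97, ABI5, OFP9, EREB50, GBP15, ZHD4, WRKY81, DOF7, MYB131, NAC25, ZFL1 and EREB69, were expressed in preps 2 and 4. GFP was expressed in all 4 preps, so each regulator had 2 libraries from separate preps and 2 GFP libraries from the same preps.

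The authors deposited 1 table of RPKM (reads scaled by row length and library size) for 30213 rows, of which 9 are PHAS loci (genomic sources of phasiRNAs) and the rest are genes of the B73 RefGen_v3 models. Per the submitters' processing notes, reads were aligned with HISAT2 2.1.0 and counted with featureCounts of Subread 1.6.3, and edgeR 3.20.9 made the RPKM. The notes do not state how reads shared between paralogs were counted. Whole read numbers were recovered from the ratios between RPKM values for 30209 of 30213 rows; 99.9999% of the values were whole within 0.05 reads. The recovered depth was 6830505 to 11875644 reads in 48 libraries, and 28153065 and 29950262 reads in the EREB69 libraries of preps 2 and 4. The deposited values carry a scaling factor per library of 0.939 to 1.09. For a row of median length, 1 read equals 0.0949 RPKM in the shallowest library and 0.0202 RPKM in the deepest. Library correlations of log2 values lay between 0.921 and 0.981, with a median of 0.968 between replicates.

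Each regulator was compared with the GFP libraries of its own 2 preps in limma 3.58.1 under R 4.3.3. A single linear model on log2(RPKM + 0.5) had 25 groups (23 regulators and GFP of each prep pair) with 25 residual degrees of freedom, and variances were moderated with a trend. Rows entered with at least 1 RPKM in at least 2 libraries, which left 28122. A row was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison and an absolute log2 change of at least 1. Errors are the SE of a limma log2 change or the SD over n = 2 libraries, and the 2 libraries of a group are separate preps, not repeat measurements of 1 prep. In data simulated from the bHLH97 comparison, 38% of 50 raised rows were called at a log2 rise of 1 and 92% at a rise of 2, with 9 unchanged rows called. The recovery of reads was tested on simulated data too, and 30210 of 30213 rows were recovered.

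Gene names came from the alias table of the Zm-B73-REFERENCE-NAM-5.0 annotation, which matched 14595 row IDs and gave 1857 of them a name. That build differs from the authors' and no coordinates of the authors' build were at hand, so no positions are given. The reference held no gene descriptions, so 32 gene lists matched by alias took the place of description patterns. The alias patterns were written after the reference was seen and before any group comparison. The regulators' own genes were looked up by name, and 5 were found (OCL4, CSD4, NAC119, HSF2 and ZFL1). Named genes were taken by a rule: the regulator's own gene, the 10 largest rises and the 10 largest falls among called rows with a name, a mean of at least 2 RPKM and the same direction in both preps, and up to 4 called members per list. Rows outside the rule are given by ID and were chosen after their values were seen. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over 736 list-by-regulator tests, with an estimated correlation and fry beside it.

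The tests, the comparisons, the named-gene rule, the block and the family pairs were fixed before the data were examined. Replicate numbers in the labels are prep numbers, so prep was added as a block in an alternative. As a check of that pairing, the difference between preps in 1 group was correlated across rows with that in another: the median was 0.131 (from −0.210 to 0.497, 66 pairs of groups) in preps 1 and 3 and 0.253 (from −0.047 to 0.474, 78 pairs) in preps 2 and 4. The other alternatives set before were pseudocounts of 0.1 and 1, no filter, 1 fit per prep pair, the other regulators as reference, median-ratio rescaling (factors 0.991 to 1.02), adjustment over all comparisons, and leaving out each library. Those added after seeing the data were limma-voom on the recovered reads, leaving out the EREB69 libraries, and a straight line through the groups by their place in the table as reference. Count-based alternatives (TMM against DESeq2 factors) applied only to a deposited count table and were not run. Regulators of 1 prep pair share both GFP libraries, so family responses were correlated mainly across prep pairs. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No library was left out of the comparisons.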

Results

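Bulk RNA-seq was collected from maize B73 leaf protoplasts that transiently expressed 1 of 23 putative regulators of reproductive phasiRNAs, or GFP alone as the control. There were 50 libraries: 2 for each regulator and 4 for GFP, spread over 4 protoplast preps. The regulators came as 11 in preps 1 and 3 and 12 in preps 2 and 4, each with the GFP libraries of its own preps as the control. Depth was 6830505 to 11875644 reads in 48 libraries, and 28153065 and 29950262 reads in the EREB69 libraries. All values below are deposited RPKM or log2 changes fitted from them, with n = 2 libraries per regulator and n = 2 per control unless stated. Intervals and errors cover the spread between preps, and reads counted without molecular identifiers are not independent molecules.

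The first question was whether each expressed regulator was visible in its own libraries. Transcripts of ocl4, a homeodomain-leucine zipper gene of the outer cell layer, stood at 2816 ± 733 RPKM (SD, n = 2) in OCL4 cells and were listed at 0 in both GFP libraries. NAC119 (first listed as CUC2) stood at 5079 ± 86.9 RPKM, the heat shock factor gene HSF2 at 2281 ± 133 RPKM, and zfl1 (first listed as fl1), a maize gene of the LEAFY type, at 9817 ± 2512 RPKM in their own libraries, and each was listed at 0 in its GFP controls. CSD4 was already expressed in GFP cells at 43.8 ± 7.48 RPKM and rose to 12915 ± 2336 RPKM. That log2 rise of 8.19 ± 0.19 (SE) had a Benjamini-Hochberg adjusted p of 2.26e-23 in limma, and all 5 own genes found by name were called. The zfl1 row also reached 154.5 ± 11.5 RPKM in ZFL2 cells, where its paralog GRMZM2G180190 stood at 6263 ± 370.3 RPKM, and how reads shared between paralogs were counted is not stated.

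For the regulators without a gene found by name, the row with the largest rise was chosen after its values were seen. In 13 of those 18 regulators 1 row rose to between 771 and 8422 RPKM. The lowest was GRMZM2G085964 in EREB69 cells, at 771 ± 22.9 RPKM against 0.574 ± 0.197, and the highest OFP16 (GRMZM2G055257) in OFP9 cells, at 8422 ± 2876 RPKM and listed at 0 in GFP. The TIFY-family gene pnFL-2 (also TIFY15, GRMZM2G005954) stood at 1725 ± 224.2 RPKM in ZIM13 cells against 12.9 ± 0.0366. GRMZM2G301089 stood at 6729 ± 1976 RPKM in bHLH103 cells against 7.78 ± 4.16, a log2 rise of 9.73 ± 1.37, but with either bHLH103 library or GFP replicate 1 left out 0 of the 2 rows called in limma for bHLH103 remained called. No such row was found in bHLH97, ABI5, EREB50, ZHD4 and WRKY81 cells, where the row with the largest fitted rise averaged 22.6, 4.19, 19.2, 10.1 and 13.6 RPKM and was not called.

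The next question was which other transcripts each regulator changed. MYB131, EREB69 and NAC29 cells had the most called rows, with 621 higher and 40 lower for MYB131, 342 higher and 0 lower for EREB69, and 244 higher and 26 lower for NAC29. OCL4 had 18 higher and NAC25 had 15 higher and 3 lower. In the other 18 regulators limma called between 0 and 6 rows, the regulator's own row included, and between 0 and 6 with any 1 library left out. No row was called by limma for bHLH97, ABI5, EREB50 and ZHD4, where 2399, 1783, 1462 and 1813 rows had an unadjusted p below 0.05 (1406.1 expected by chance), and limma-voom on the recovered reads called 0 in each. With prep as a block, totals reached 133 in HSF2 (6 without it), 153 in DOF25 (3 without it) and 8 in ZHD4, and the other totals of these 18 stayed between 0 and 13. The 124 higher rows of HSF2 and 120 of DOF25 had 55 in common (0.529 if independent). Both comparisons use the same GFP libraries, and the regulators stand at places 10 and 11 in the table, so these totals are not independent. For EREB69, 2614 rows had an unadjusted p below 0.05 in limma, and limma-voom called 320 higher and 10 lower.

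**Figure D1:**
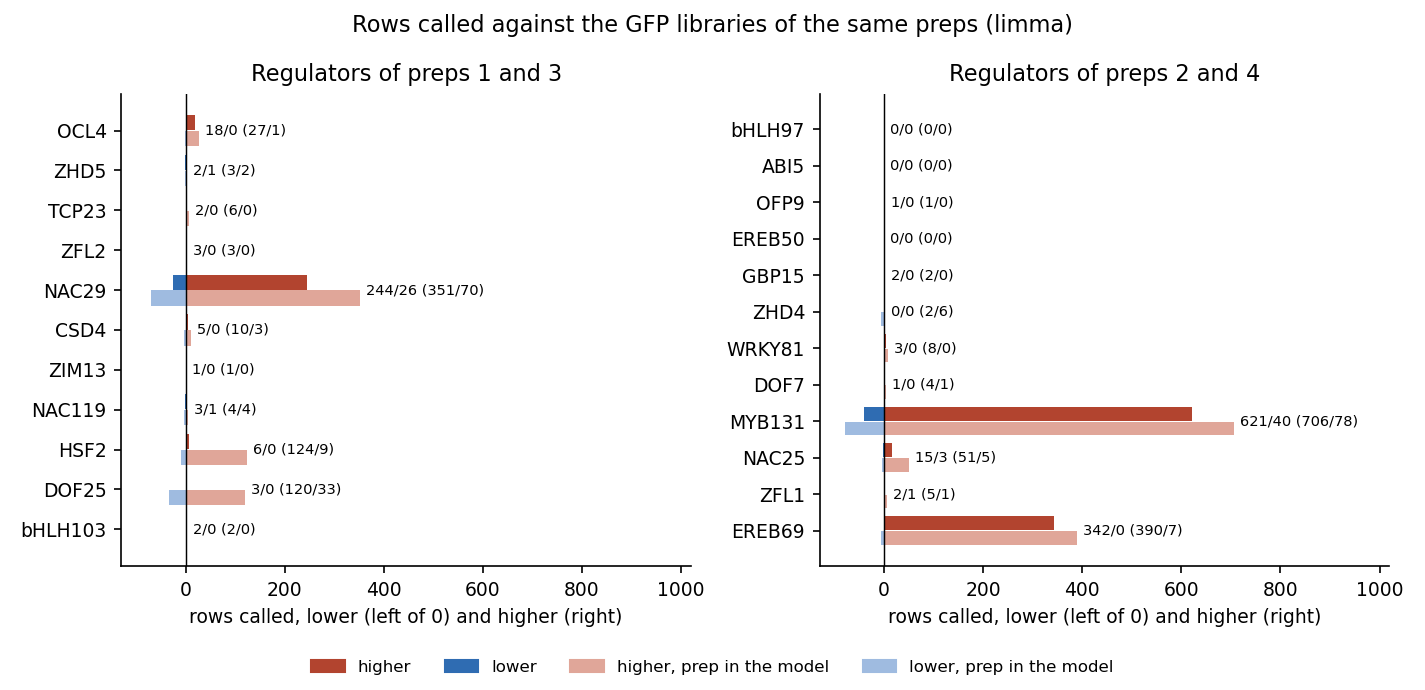
Number of rows called by limma as higher (right of 0) or lower (left of 0) for each of the 23 regulators against the 2 GFP libraries of its preps, with dark bars for the comparison as fixed and pale bars for prep as a block, the counts printed beside them as higher/lower. MYB131, EREB69 and NAC29 have 621, 342 and 244 higher rows, and 18 of the 23 regulators have 6 or fewer called rows.

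MYB131 cells gained transcripts of some wall and phenylpropanoid genes. Laccase-13 (GRMZM2G132169), a laccase of the kind that polymerises lignin, stood at 78.1 ± 34.8 RPKM against 0.602 ± 0.416 in GFP cells, a log2 rise of 6.13 ± 0.31 (SE). A further Laccase-13 row, GRMZM5G814718, stood at 7.94 ± 6.17 RPKM and was listed at 0 in GFP, and the MYB gene myb31 (first listed as MYB1_2), a regulator of lignin genes, rose by 3.08 ± 0.32. PAL1, which encodes phenylalanine ammonia-lyase at the entry to the pathway, fell outside the naming rule and was chosen after its values were seen; it stood at 416 ± 146 RPKM, a rise of 1.85 ± 0.27. In the phenylpropanoid and lignin list, 5 of 16 tested members were higher (6 when adjusted over the list alone) and 11 were not called by limma. The higher members include GRMZM2G132169, GRMZM5G814718 and GRMZM2G336337 (a rise of 2.22 ± 0.26), which share the alias Laccase-13, and myb31. The count is thus not of as many separately named genes. The list's rise had an adjusted p of 2.21e-06 in limma camera, and adjusted p = 0.312 with an estimated correlation.

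Among the cellulose and secondary wall genes, 3 of 21 were higher in MYB131 cells, led by the cellulose synthase CesA-8 (1.71 ± 0.22, 9.97 ± 1.56 RPKM against 2.69 ± 0.240) and XAT2 (1.39 ± 0.20). CesA-7 rose by 1.03 ± 0.23 and lost its call without MYB131 replicate 2 or GFP replicate 4 (from 0.72 to 1.33 with 1 library left out), and with the other regulators as reference (0.47). That list had a limma camera adjusted p of 0.0129, and adjusted p = 0.719 with an estimated correlation, and did not pass with the other regulators (0.0557) or the line by place (0.155) as reference. The ethylene list had 3 of 27 members higher (4 adjusted over the list alone), the factors EREB85 (3.63 ± 0.28) and EREB20 (2.08 ± 1.04 RPKM against 0.0833 ± 0.118) and the ACC oxidase gene acco20 (1.79 ± 0.33), which lost its call without MYB131 replicate 2 (1.34). Its limma camera adjusted p was 0.00483, and adjusted p = 0.719 with an estimated correlation. The chalcone synthase gene c2, first enzyme of flavonoid synthesis, rose by 3.18 ± 0.34 to 6.93 ± 5.71 RPKM, but was the 1 called gene of 9 in the flavonoid list, which did not pass. Other large named rises were znod1 (23.3 ± 10.1 RPKM, listed at 0 in GFP), myb2 (5.44 ± 0.28), bZIP7 (2.92 ± 0.34) and ANAC010 (2.19 ± 0.33), and no lower row met the naming rule. Without MYB131 replicate 2 the total fell from 661 to 420 rows, of which 365 were among the 661.

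NAC29 cells gained transcripts of starch synthesis genes. The starch synthase gene du1 rose from 0.897 ± 0.101 to 5.57 ± 0.612 RPKM, a log2 rise of 2.12 ± 0.26 with a limma adjusted p of 1.17e-05. A further starch synthase gene, ss1, rose by 1.64 ± 0.27 to 15.9 ± 0.580 RPKM. AGP2 rose by 1.76 ± 0.35 and lost its call without GFP replicate 1, NAC29 replicate 1 or NAC29 replicate 3 (from 1.56 to 1.96 with 1 library left out). These were 3 of 19 tested members of the starch and sugar list (3 adjusted over the list alone), and 16 were not called by limma. The list had a limma camera adjusted p of 0.0351, and adjusted p = 0.748 with an estimated correlation, and did not pass with the other regulators (0.386) or the line by place (0.327) as reference.

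The auxin response factor gene ARF18 rose by 1.25 ± 0.15 in NAC29 cells (27.1 ± 4.66 RPKM against 11.03 ± 0.436) and bHLH55 by 1.34 ± 0.20, and both kept their call with any 1 library left out. JAZ9, a jasmonate signalling repressor gene, rose by 2.18 ± 0.48 and lost its call without GFP replicate 3 or NAC29 replicate 3 (from 1.65 to 2.71 with 1 library left out). The histone gene H4C13 fell by 1.12 ± 0.27, a call lost without GFP replicate 1 or 3 or NAC29 replicate 1 or 3 (from −1.20 to −1.04) and with the other regulators as reference, where the change was −0.36. NAC29's total of 270 fell whichever of its own or its GFP libraries was left out. The fall thus does not point to a single library, and fewer libraries also weaken the test. With prep as a block the total was 421.

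EREB69 cells gained transcripts nearly silent elsewhere: 36 rows with at least 1 RPKM in both EREB69 libraries averaged under 0.1 RPKM over all other libraries. The zein gene dzs18, for a seed storage protein, stood at 9.40 ± 6.84 RPKM and was listed at 0 in both GFP libraries, with a limma adjusted p of 4.87e-10. RTE2 rose by 2.35 ± 0.31, stv2 by 2.20 ± 0.26, GFT1 by 2.17 ± 0.31 and gar1 by 2.03 ± 0.27, the last to 26.2 ± 15.1 RPKM. RADIALIS rose by 1.78 ± 0.27 and HST by 1.84 ± 0.24, from 4.40 ± 0.362 to 17.3 ± 4.74 RPKM. These 7 genes kept their call with any 1 library left out, and RADIALIS lost it with a pseudocount of 0.1. The starch and autophagy lists passed upward and the heat shock and ribosomal lists downward in limma camera, though their members were not called singly, and the lowest was adjusted p = 0.719 with an estimated correlation. The starch and heat shock lists did not pass with the other regulators as reference (0.233 and 0.211). Without EREB69 replicate 2 the total fell from 342 to 140 rows, and both EREB69 libraries were on average 3.07 times as deep as the median of the others.

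**Figure D2:**
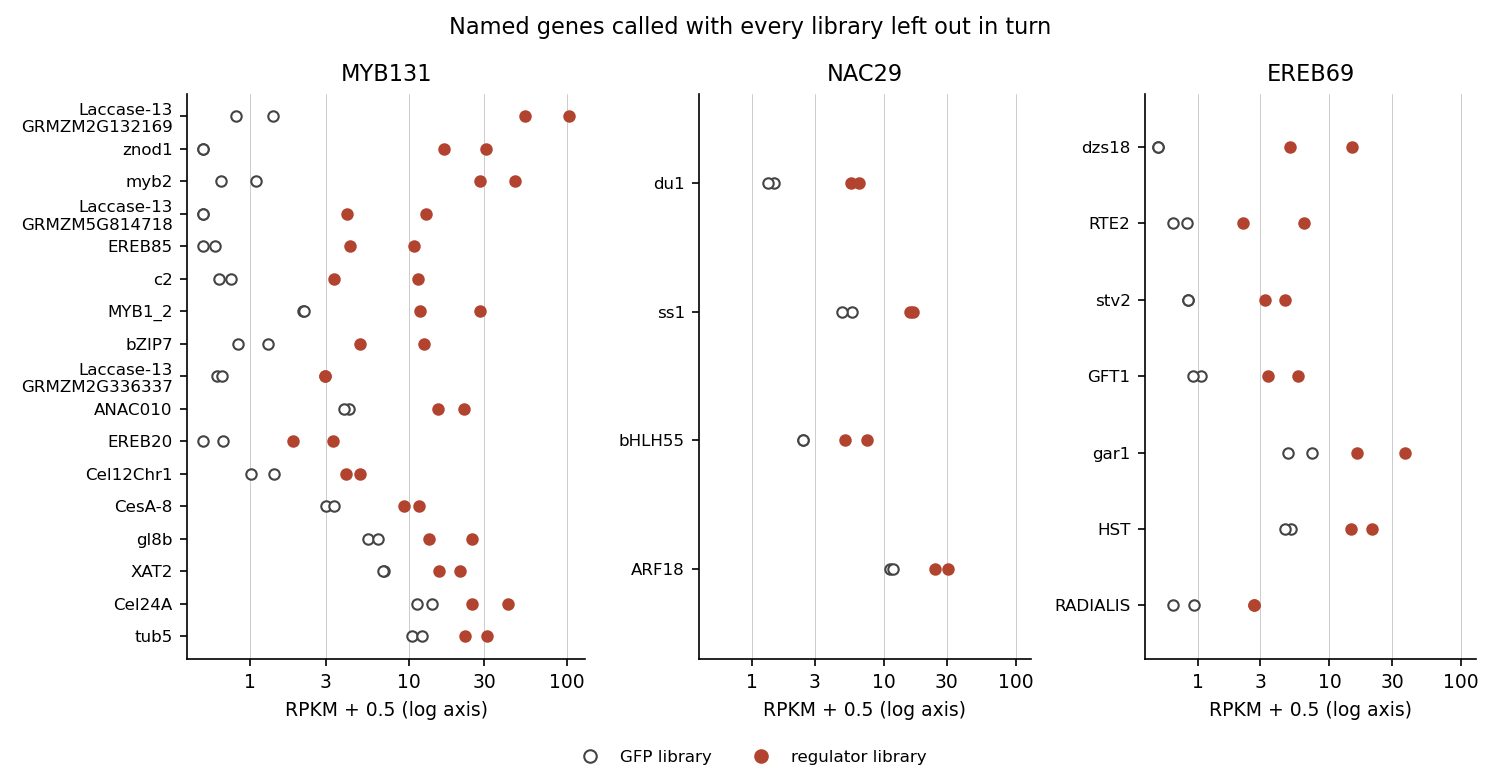
RPKM + 0.5 (log axis) of the named genes in MYB131, NAC29 and EREB69 cells that kept their call with any 1 library left out, with 1 filled point per regulator library (n = 2) and 1 open point per GFP library (n = 2). Both regulator libraries lie above both GFP libraries for each gene, widest for Laccase-13 (GRMZM2G132169) with means of 78.1 and 0.602 RPKM.

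OCL4 and NAC25 changed fewer rows. In OCL4 cells ocl4 was the only named gene among 18 higher rows, and the total was 7 without GFP replicate 3, 7 without OCL4 replicate 3, 31 without OCL4 replicate 1 (17 higher and 14 lower, so that the absence of lower calls rests on that library) and 28 with prep as a block. With the other regulators as reference OCL4 had 24 higher and 5 lower. In NAC25 cells CesA-7 rose by 1.12 ± 0.23 (5.13 ± 1.28 RPKM against 2.11 ± 0.767) with a limma adjusted p of 0.0441, a call lost without NAC25 replicate 2 or GFP replicate 4 (from 0.82 to 1.43 with 1 library left out) and with the other regulators as reference (0.57). The cellulose and secondary wall list passed at 0.0354 in limma camera with 1 of 21 members higher, and adjusted p = 0.719 with an estimated correlation, and did not pass with the other regulators as reference (0.183). NAC25's total of 18 was 36 without NAC25 replicate 4, 56 with prep as a block, and 59 against the line by place, of which 26 were higher and 33 lower. In GBP15 cells both called rows, GRMZM2G036966 and GRMZM2G392516 (122 ± 12.4 RPKM against 2.73 ± 1.03), were called with any 1 library left out. GRMZM2G025200 was called higher for 6 of the 11 regulators of preps 1 and 3, where the GFP libraries held 0.962 and 1.18 RPKM and the regulators 4.40 ± 1.09 (SD, 22 libraries), and it lost these calls with the other regulators as reference.

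The study asked about 21-nt reproductive phasiRNAs, so the PHAS rows were examined next. Poly(A) reads counted in the 24PHAS_NO166 row were abundant in leaf protoplasts of every group, at 255 ± 37.0 RPKM (SD, 50 libraries, from 186 to 359). No positions of the authors' build were at hand, so which transcript these reads come from was not checked. The 3 sources of 21-nt phasiRNAs in the table were low: 21PHAS_NO232 averaged 4.85 ± 1.52 RPKM, 21PHAS_NO556 1.09 ± 0.358 and 21PHAS_NO583 0.929 ± 0.530. The 24-nt sources 24PHAS_NO160, 24PHAS_NO8 and 24PHAS_NO42 averaged 4.11, 3.19 and 0.872 RPKM, and 24PHAS_NO35 and 24PHAS_NO44, at 0.427 and 0.279, were too low to test. Changes against GFP ran from −0.79 ± 0.45 (24PHAS_NO42 in EREB69) to 0.88 ± 0.51 (24PHAS_NO8 in OCL4), and 21PHAS_NO232 had its largest in NAC29 at 0.68 ± 0.45. In 161 limma tests of 7 PHAS rows by 23 regulators 0 were called, 0 with adjustment over the list alone, 0 with limma-voom and 0 had an unadjusted p below 0.05, and the lowest adjusted p was 0.525. Apart from 24PHAS_NO166, the tested rows held means of 5.58 to 39.2 reads per library and SE of up to 0.59. The simulation drew its raised rows from all 28122 rows, so its 38% called at a rise of 1 is not the power for rows this low. Changes of 1 log2 unit in them are not excluded, and the simulation does not show which larger changes would have been called.

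**Figure D3:**
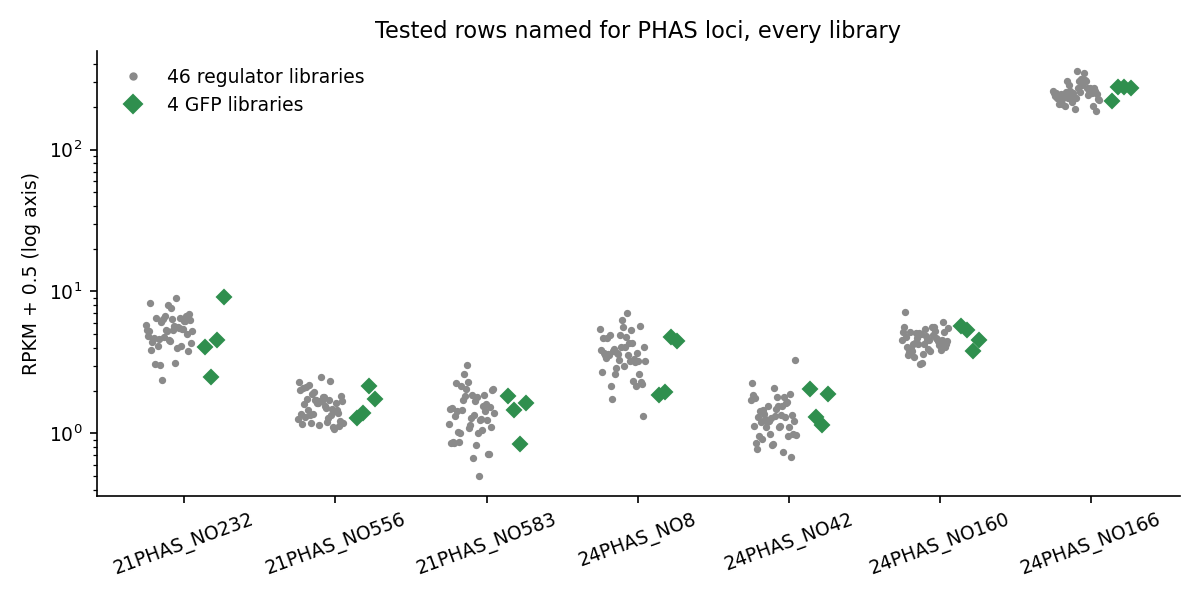
RPKM + 0.5 (log axis) of the 7 tested PHAS rows, with 1 grey point for each of the 46 regulator libraries and 1 green diamond for each of the 4 GFP libraries. 24PHAS_NO166 lies between 186 and 359 RPKM in all libraries, and 21PHAS_NO232 averages 4.85 RPKM.

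Genes of the small RNA machinery were mostly expressed at a level that could be tested. The Dicer gene dcl1 averaged 25.0 ± 2.02 RPKM over the 50 libraries, the RNA-dependent RNA polymerase gene rdr6 3.65 ± 0.859 and argonaute1 6.05 ± 0.914, while lbl1, which acts with rdr6 in making trans-acting siRNAs, was at 0.276 and mop1 at 0.523, and neither was tested. Of 299 limma tests on 13 rows, 2 were called, both higher, with 2 adjusted over the list alone within each regulator and 1 over all regulators. They were HST in EREB69, whose symbol has no full name in the reference, so that its place in this list rests on the symbol alone, and the DNA methyltransferase gene dmt106 in NAC29, which rose by 1.17 ± 0.30 (7.39 ± 0.167 RPKM against 3.04 ± 0.673; limma adjusted p 0.0420) and lost its call without GFP replicate 1 or 3 or NAC29 replicate 1 or 3 (from 0.97 to 1.36) and with the other regulators as reference. The small RNA machinery list passed in 0 of 23 regulators in limma camera and in 0 with an estimated correlation, with 8 of its 299 single tests at an unadjusted p below 0.05.

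Across all 32 lists, 88 of 736 camera tests passed, 57 upward and 31 downward, in 22 of the 23 regulators. Ribosomal protein genes were lower in 16 regulators, of which 4 passed downward with the other regulators as reference too while OCL4 and ZHD5 turned to a passed rise, and most in bHLH103 with a median change of −0.54 over 37 members, none called singly (limma camera adjusted p 1.34e-12, and adjusted p = 0.716 with an estimated correlation). Pathogenesis-related and defence genes were higher in 13, most in bHLH97, where 24 of 25 members had positive values (limma camera adjusted p 5.68e-05, and adjusted p = 0.719 with an estimated correlation). Jasmonate genes were higher in 7, led by HSF2, and autophagy genes higher in 7 and lower in 1. The jasmonate list holds pnFL-2, the row with the largest rise in ZIM13 cells. Heat shock proteins were lower in 6, led by bHLH97 with a median of −0.63, and higher in OCL4, with a median of 0.24. Histones and cell cycle genes were lower in 6, the starch list higher in 5, the reference genes higher in 4 and abscisic acid genes in 3. None of the histone, starch, reference gene and abscisic acid passes held in the same direction with the other regulators as reference. There 3 of the 13 defence, 3 of the 7 jasmonate, 4 of the 8 autophagy and 5 of the 7 heat shock passes held. Defence and jasmonate genes each passed downward in 2 regulators with that reference. Benzoxazinoid and terpenoid, gibberellin and brassinosteroid, and cellulose genes were higher in 2 each, and glutathione and redox genes lower in 2. The phenylpropanoid and ethylene lists (MYB131), cytokinin (HSF2), wall loosening (ZHD4; 0.0519 with prep as a block) and cuticle (OCL4, with ocl4 a member) lists were higher in 1 each. With an estimated correlation none of these lists passed, and the lowest was adjusted p = 0.312 for phenylpropanoid genes in MYB131.

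The list of tested regulators rose in 6 (OCL4, ZFL2, CSD4, NAC119, HSF2 and ZFL1), where the expressed gene or its paralog is itself a member. With an estimated correlation 4 of the 88 passed in limma camera, all of them from this list, and 0 of the 82 others, while limma's fry passed 16. Comparisons within a prep pair share the same 2 GFP libraries, so lists that passed in many regulators are not independent results, and 25 of the 88 passed in the same direction with the other regulators as reference. Ribosomal protein genes also fell with place in the table over the regulators of preps 1 and 3 (limma camera adjusted p 4.21e-12, and adjusted p = 0.478 with an estimated correlation) and rose in preps 2 and 4 (0.00793, and adjusted p = 0.684 with an estimated correlation). The lists for anaerobic response, auxin, bundle sheath, mesophyll, endoplasmic reticulum folding, flavonoid, light harvesting, MADS-box, nitrogen, PHAS loci, seed storage, small RNA and vascular genes passed in no regulator. In MYB131, 2 of 7 tested members of the C4 mesophyll list were higher and 5 were not called by limma: pdk1 rose by 1.39 ± 0.36 (427 ± 129 RPKM against 163 ± 54.4) and lost its call without MYB131 replicate 2 or GFP replicate 4 (from 1.05 to 1.74 with 1 library left out). The other member, PPDK, matched the list by alias but is first listed as CYPPDKZM2, whereas pdk1 is first listed as C4ppdkZm1. PPDK (GRMZM2G097457) rose by 1.30 ± 0.33, to 1.71 ± 0.270 RPKM against 0.405 ± 0.197, and lost its call without MYB131 replicate 2, MYB131 replicate 4 or GFP replicate 4 (from 1.07 to 1.52). Its call was also lost with the other regulators as reference.

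Regulators of 1 family were compared to ask whether their log2 changes ran alike across 28122 rows, which are not independent replicates. Responses to bHLH97 and bHLH103 were the most alike of all 132 pairs that share no control, with a Pearson r of 0.382 (Spearman 0.431), but r was −0.00228 when a straight line by place in the table was the reference. ZHD4 with ZHD5 reached 0.161, DOF7 with DOF25 0.137, NAC25 with NAC29 0.075 and ZFL1 with ZFL2 0.058, against a median of 0.0587 for the 132 pairs, and NAC25 with NAC119 stood near the bottom at −0.150. With the other regulators as reference the values were 0.312 for NAC25 with NAC29, 0.259 for bHLH97 with bHLH103 and 0.244 for ZFL1 with ZFL2. They were 0.165 for DOF7 with DOF25, 0.145 for ZHD4 with ZHD5 and −0.116 for NAC25 with NAC119. Without the 93 rows with a log2 change of 4 or more in any regulator, ZFL1 with ZFL2 fell to 0.143. NAC25 with NAC29 then stood at 0.331 and bHLH97 with bHLH103 at 0.254. The zfl1 row itself was called higher in both ZFL1 and ZFL2 cells. EREB50 with EREB69 had r = 0.464 (covariance 0.0736) and NAC29 with NAC119 0.474 (covariance 0.0823). These pairs share both controls, which alone gave 0.501 ± 0.0107 (covariance 0.0534 ± 0.00166) in simulation, and part of the excess in covariance may come from the shared controls, since 2 GFP libraries allow no split. Pairs within preps 1 and 3 had a median r of 0.600 (median covariance 0.0894) and those within preps 2 and 4 of 0.511 (0.0722). NAC29 with NAC119 lay below its median in both, and EREB50 with EREB69 lay below in r and close to it in covariance. Neither pair stood out among pairs of its preps. Their r was −0.179 and −0.070 with the other regulators as reference, but each regulator is then part of the other's reference, which alone pulls r below 0.

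**Figure D4:**
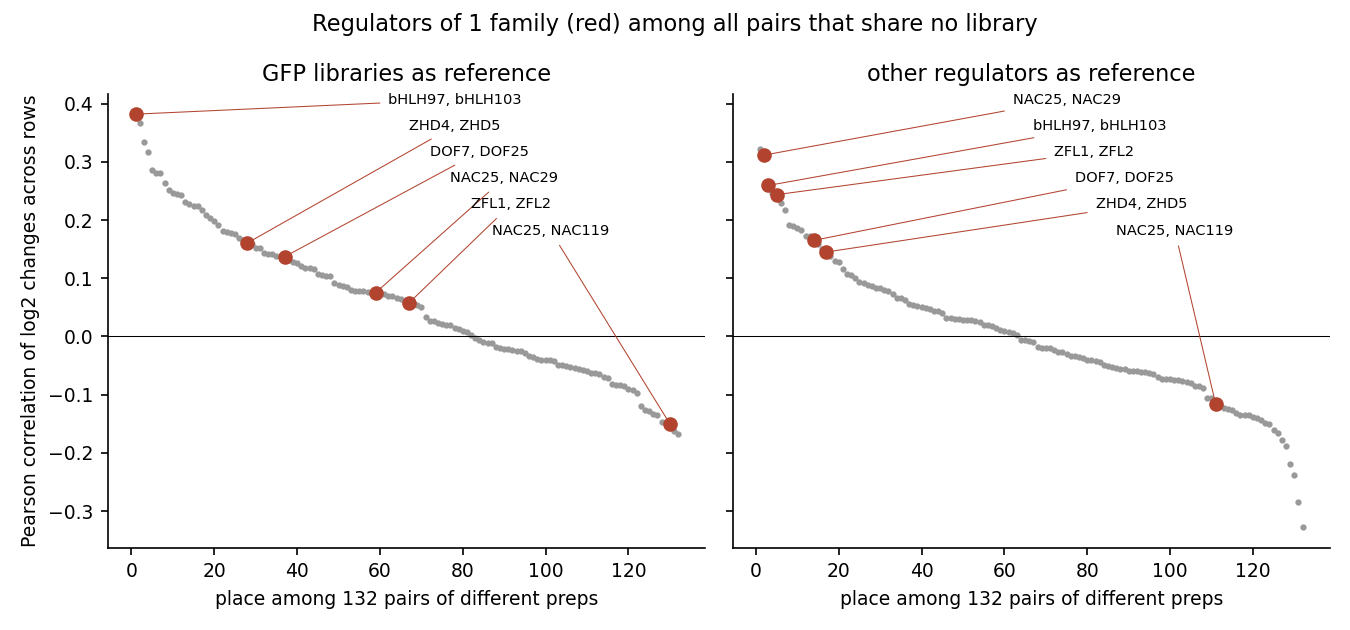
Pearson correlation across rows of log2 changes (vertical axis, no unit) against place among the 132 pairs of regulators that share no library, 1 grey point per pair and family pairs in red, with GFP (left) or the other regulators (right) as reference. The pair of bHLH97 and bHLH103 is highest at 0.382 on the left, and NAC25 with NAC29 is the second on the right at 0.312.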

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

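The tests of chance order and of chance split, the thinning, scaling and batch tests on the EREB69 calls and the search for a trend by place in the table were chosen only after the result was seen, although rescaling and leaving out each library were alternatives set before. Among 72 values compared over the 4 GFP libraries, 8 had 1 library far from the other 3, where 3.6 would be marked by chance, since chance flags about 1 in 20; for 3 of the 8, at 0 in the other libraries, any value above 0 would be marked. The GFP library of prep 4 had 357 rows at 0 against 444 to 461 in the others. 24PHAS_NO166 stood at 219 RPKM in GFP of prep 1 against 270 to 277. The NAC119 gene was at 0.0777 RPKM in GFP of prep 2 and at 0 in the others. The HSF2 gene was at 0.0583 RPKM in GFP of prep 2 and at 0 in the others. EREB85 was at 0.101 RPKM in GFP of prep 4 and at 0 in the others. pnFL-2 stood at 15.5 RPKM in GFP of prep 2 against 12.6 to 12.9. XAT2 stood at 5.24 RPKM in GFP of prep 1 against 6.36 to 6.51. MADS70 stood at 4.23 RPKM in GFP of prep 1 against 2.35 to 2.46. With prep in the model, limma called 0 rows between the 4 GFP libraries and the 46 others (4099 at an unadjusted p below 0.05), so that all 100 splits that took 1 library of each prep had as many by construction and decide nothing, and the highest other had 111.

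In preps 1 and 3, limma found 562 rows (307 rising, 255 falling), and in preps 2 and 4 282 rows (78 rising, 204 falling), whose level followed the place of the 11 regulators in the table, with 3105 and 384 when GFP was included; EREB69 was left out of preps 2 and 4. Chance order is argued against in preps 1 and 3, where 1 of 100 orders, the real one, gave as many and the highest other gave 15. It is not excluded there, since 100 orders allow no finer bound and slopes fitted in each prep correlated at only 0.0528 across rows. In preps 2 and 4 chance order stays open: 3 of 100 orders gave as many, the real one included, and the highest other gave 863 (slopes correlated at 0.409). That higher count points to a structure of those libraries that was not tested. Sequencing depth is argued against as the whole cause in preps 1 and 3, where 1285 rows had a trend with log2 reads in the model, while in preps 2 and 4 5 rows were left and sequencing depth cannot be told apart from place, because reads fell along the table in prep 4. Whether a single regulator carries each trend cannot be told, since the count is unstable (the rule set before would have kept it as a cause, and leaving it open where several regulators do so was chosen after the counts were seen): leaving out OCL4 or DOF25 in preps 1 and 3, or bHLH97, EREB50 or NAC25 in preps 2 and 4, left 0 rows in limma (5456 and 5921 had an unadjusted p below 0.05 with all 11), and leaving out another left 23 to 820 and 1 to 1955. Order of handling stays open as a candidate explanation, since the labels give no dates. Of the 19 rows with a trend in both prep pairs (5.64 if independent), 0 had the same direction. That does not decide the question, because a drift need not run the same way in separate preps, and no biological explanation was tested.

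EREB69 cells had 342 rows higher and 0 lower in limma (2614 at an unadjusted p below 0.05; limma-voom called 320 higher and 10 lower), from libraries 3.07 times as deep as the median of the others. Depth is argued against as the cause of the calls, because EREB69 reads thinned to the median depth in 10 draws gave 324 to 358 higher rows and at most 8 lower, with a median of 312 also called at full depth. The authors' scaling factors are argued against as the cause of the calls, which need a log2 change of at least 1. These factors were 1.01 and 1.03 in the EREB69 libraries and 0.994 and 1.01 in the GFP libraries of preps 2 and 4. Median-ratio rescaling gave 344 higher rows, but changed libraries by factors of only 0.991 to 1.02, so it decides little by itself. A separate library batch cannot be told apart from an effect of EREB69, because no other library has this depth and the labels name no batch. The expressed EREB69 protein may have raised dzs18, HST and the rest, and that stays open as untested, as does the reliance on EREB69 replicate 2, without which 140 rows were called.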

How the results depend on the processing

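The tests with limma-voom, without the EREB69 libraries, with the line by place as reference and, for lists, with the other regulators as reference were chosen only after the result was seen. Of 66 pairs of a named gene and a regulator, all kept their direction in 966 refits: 819 kept the call and 147 lost it, 0 turned. A gene named in several regulators counted once in each. Of the pairs, 66 were called with the block and 56 with the other regulators as reference. The kept direction was partly fixed in advance. Genes named for the largest changes were chosen for the same direction in both preps. The block and the adjustment over all comparisons also left each log2 change as it was. Median-ratio rescaling, leaving out the EREB69 libraries and thinning EREB69 moved no count of called rows by more than 1.5 times. With the block 87 of the 88 list tests passed again, the wall loosening list in ZHD4 did not (adjusted p 0.0519) and 21 others passed, 108 in all; apart from these and the counts below, the block changed no other call of a named gene. Where a library is left out, the lone library of its group is assumed to vary like the other groups. Depth limits rows near 1 RPKM, where 1 read is 0.0949 RPKM in the shallowest library. Except where a setting changes the number of tests or libraries by construction, the cause was not tested.

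Totals of called rows with the replicate block were 28 in OCL4, 5 in ZHD5, 6 in TCP23, 421 in NAC29, 13 in CSD4, 8 in NAC119, 133 in HSF2, 153 in DOF25, 8 in ZHD4, 8 in WRKY81, 5 in DOF7, 56 in NAC25 and 6 in ZFL1. With the other regulators as reference they were 29 in OCL4, 7 in TCP23, 7 in ZFL2, 11 in CSD4, 7 in ZIM13, 7 in NAC119, 16 in HSF2, 7 in DOF25, 6 in bHLH103, 3 in bHLH97, 4 in ABI5, 4 in OFP9, 3 in EREB50, 7 in GBP15, 2 in ZHD4, 7 in WRKY81, 3 in DOF7, 35 in NAC25 and 6 in ZFL1. Adjusted over all comparisons they were 6 in ZHD5, 6 in TCP23, 5 in ZFL2, 145 in NAC29, 3 in ZIM13, 9 in NAC119, 17 in HSF2, 6 in DOF25, 4 in bHLH103, 3 in bHLH97, 2 in ABI5, 3 in OFP9, 4 in GBP15, 7 in ZHD4, 8 in WRKY81, 4 in DOF7, 30 in NAC25 and 8 in ZFL1. With the line by place they were 6 in ZHD5, 5 in TCP23, 6 in ZFL2, 9 in CSD4, 5 in ZIM13, 10 in HSF2, 6 in DOF25, 9 in bHLH103, 4 in bHLH97, 2 in ABI5, 2 in EREB50, 5 in GBP15, 5 in ZHD4, 15 in WRKY81, 8 in DOF7, 59 in NAC25 (26 higher and 33 lower) and 99 in ZFL1 (7 higher and 92 lower). By limma-voom they were 1 in ZHD5, 2 in NAC119, 3 in HSF2, 1 in bHLH103 and 0 in WRKY81 (1415 at an unadjusted p below 0.05 in limma). With 1 fit per prep pair they were 3 in ZIM13, 7 in NAC119, 21 in HSF2, 5 in DOF25, 0 in WRKY81 and 4 in NAC25. With a pseudocount of 0.1 they were 2 in ZIM13, 3 in HSF2, 2 in ZHD4 and 11 in NAC25, and with 1 they were 1 in ZHD5 and 2 in NAC119. With no filter they were 1 in ZHD5 and 2 in DOF7. The totals they compare with were OCL4 18, ZHD5 3, TCP23 2, ZFL2 3, NAC29 270, CSD4 5, ZIM13 1, NAC119 4, HSF2 6, DOF25 3, bHLH103 2, OFP9 1, GBP15 2, WRKY81 3, DOF7 1, NAC25 18, ZFL1 3, and 0 by limma in bHLH97, ABI5, EREB50 and ZHD4 (2399, 1783, 1462 and 1813 at an unadjusted p below 0.05; 0 by limma-voom).

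With 1 library left out totals ran from 7 to 31 in OCL4, 105 to 182 in NAC29, 420 to 734 in MYB131, 140 to 343 in EREB69, 12 to 36 in NAC25, 1 to 2 in ZHD5, 1 to 2 in TCP23, 2 to 5 in ZFL2, 3 to 4 in CSD4, 1 to 1 in ZIM13, 2 to 2 in NAC119, 1 to 4 in HSF2, 2 to 4 in DOF25, 0 to 1 in bHLH103, 1 to 3 in bHLH97, 1 to 2 in ABI5, 1 to 6 in OFP9, 0 to 2 in EREB50, 3 to 5 in GBP15, 0 to 2 in ZHD4, 0 to 2 in WRKY81, 1 to 3 in DOF7 and 2 to 6 in ZFL1. Against 88 list tests passed with GFP as reference, 4 passed with an estimated correlation (all among the 88), 16 by fry (13 among the 88) and 49 with the line by place (20 among the 88, EREB69 left out). With the other regulators as reference 4 turned direction: ribosomal proteins rose in OCL4 (adjusted p 0.00200) and ZHD5 (0.00528), and tested regulators fell in ZFL2 (0.0175) and NAC119 (0.0290), where the mean of the reference holds the expressed genes of other regulators. Correlations with that reference were 0.244 for ZFL1 with ZFL2 (0.143 without rows that change by 4 or more), 0.312 for NAC25 with NAC29, −0.070 for EREB50 with EREB69 and −0.179 for NAC29 with NAC119. EREB50 with EREB69 and NAC29 with NAC119 no longer share GFP there, but each regulator is part of the other's reference. That alone pulls their r below 0, so these values do not show what is left without a shared control. With the line they were −0.00228 for bHLH97 with bHLH103, 0.207 for NAC25 with NAC29 and −0.0190 for NAC25 with NAC119.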

Other observations

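The test of the mean place of family pairs was chosen only after the result was seen. Transcripts raised by regulators from different preps overlapped. These comparisons share no regulator or GFP library, but 1 fit over all groups gave each row the same error in all of them. MYB131 and NAC29 both raised 48 rows, against 5.39 if their lists were independent, with JAZ9, acco20, EREB85 and CesA-7 among them. In NAC29 each of these genes lost its call with 1 or another library left out (lowest rises 1.65, 1.57, 0.99 and 0.97). In MYB131 JAZ9, acco20 and CesA-7 did too, while EREB85 kept its call. NAC29 and EREB69 both raised 22 rows (2.97 if independent), and NAC25 and NAC29 both raised 5 (0.130 if independent), with CesA-7 among them. CesA-7 was not called in MYB131 (0.47), NAC29 (0.84) or NAC25 (0.57) with the other regulators as reference. Independence was not tested beyond these expected numbers, since co-expressed rows do not vary separately. A row with a small error is also called more easily in both lists, and overlaps were not counted from 1 fit per prep pair.

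MYB131 cells also held transcripts that were nearly silent in the rest of the study. In them 70 rows with at least 1 RPKM in both libraries averaged under 0.1 RPKM over all other libraries, the highest being GRMZM2G015603 at 126 RPKM, chosen after its values were seen. EREB69 had 36 such rows, OCL4 had 3, DOF25 had 2 and NAC29, NAC119, HSF2 and OFP9 had 1 each, which in OCL4, DOF25, HSF2 and OFP9 include the expressed gene or the row with the largest rise; the other groups had 0. Stress-related genes differed by prep pair along the table: heat shock proteins fell with place in preps 1 and 3 (limma camera adjusted p 4.64e-09, and adjusted p = 0.478 with an estimated correlation) and rose in preps 2 and 4 (0.0255, and adjusted p = 0.708 with an estimated correlation). Defence genes rose with place in preps 1 and 3 (0.0249, and adjusted p = 0.638 with an estimated correlation) and fell in preps 2 and 4 (2.97e-07, and adjusted p = 0.478 with an estimated correlation).

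Regulators of 1 family may share responses. The 6 family pairs that share no control had a mean place of 25.3 among 132 pairs with the other regulators as reference (permutation p = 0.00252, 100000 draws, not adjusted), of 34.0 by Spearman correlation (permutation p = 0.0161) and of 25.3 among 121 pairs with the line by place (permutation p = 0.00418), but of 53.7 with GFP as reference (permutation p = 0.207). Reads of the expressed genes themselves are argued against as the cause, because without rows that change by 4 or more the mean place was 29.3 (permutation p = 0.0062). The high correlation of bHLH97 and bHLH103 was not due to a few rows, since it was 0.318 without the top 1% of rows, but the trend by place could account for it: with the line as reference the pair was at place 61. The draws did not exchange family labels among regulators, and pairs that share a regulator or a reference are not independent, so the p do not test family as such. In bHLH97 and ZHD4 limma called no row without the block (2399 and 1813 at an unadjusted p below 0.05), and no strongly raised row was found. The 6 pairs share NAC25 in 2 of them, these were 5 versions of 1 test, and shared DNA-binding targets stay a hypothesis.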
